A study of Arabidopsis thaliana with 42 samples.

How the data were processed

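RNA was measured in whole seedlings of 19 natural accessions of Arabidopsis thaliana, the founders of the MAGIC population, a set of intercrossed lines used to map traits. Per the labels' protocols, seeds were stratified for 5 days at 4 C, and plants grew on soil for about 11 days at 20 C under 16 hours of light and 8 hours of dark. Libraries of polyadenylated RNA were made with a protocol adapted from the Illumina mRNA kit, per the labels. Each accession had 2 libraries labelled as biological replicates, 38 in all, and Col-0, the accession of the reference genome, had 4 more labelled as technical replicates, which gives 42 libraries. Labels place the biological libraries on 5 pairs of lanes of runs 38 and 39, with 3 or 4 accessions to a pair, and the technical libraries on lane 7 of run 35. Accession and lane pair are therefore partly confounded. Both Zu-0 libraries were on lane 1 of run 39, so their spread holds no difference between lanes. The hour of harvest was not given in the sources used here.

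The deposited files hold RPKM, defined per the file headers by reads, exon model length and mapped reads: a value is scaled to the length of the exon model and to the mapped reads of the library. The submitters' processing notes name the genome builds TAIR9 and TAIR10. The aligner, the counting tool, the use of strand and the treatment of reads with several matches were not given in the sources used here. Files of the biological libraries list 65238 features, namely 33323 nuclear genes, 31189 transposable elements, 447 genes the authors called new, 146 mitochondrial genes and 133 plastid genes. They also hold the code -1, whose meaning was not given; it was read as no value. Between 6133 and 7304 features per library carried it, including the plastid and mitochondrial genes in all 38. The 6133 was the count of both Col-0 libraries, and those of the other accessions held 6633 (Po-0 replicate 1) to 7304 (Can-0 replicate 2). Files of the technical libraries list 28691 genes, with values for both organelles and no code, so they came from another feature set and were compared with the others by description alone. An RPKM value also depends on the feature length, and for accessions other than Col-0 on how reads that differ from the reference were aligned, which the files do not show.

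Depth was estimated from the values, since a gene with few reads holds a whole multiple of what 1 read is worth. Ratios of low values between libraries and the exon lengths of the TAIR10.1 annotation gave 1240000 reads in Ws-0 replicate 2 to 4920000 in Ct-1 replicate 2, with a median of 3630000. Of genes above 0 and under 1 RPKM in both libraries of an accession, 99.7% in Col-0 and 70.2% to 77.1% in the other 18 accessions had a ratio of whole numbers up to 20, within a relative tolerance of 0.0002. Whole reads were therefore not recovered outside Col-0, and no count test was run. At these depths 3 reads on 1500 bases were worth 0.406 to 1.61 RPKM; this floor covers counting error only. Between 17055 and 17846 nuclear genes and genes called new per library reached 1 RPKM, transposable elements not counted. The 10 most abundant features held 8.09% to 10.3% of the summed RPKM.

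Genes entered the tests with at least 1 RPKM in at least 2 of the 38 libraries, which left 20669 genes, 20316 nuclear and 353 called new by the authors. Another 893 transposable elements passed the same filter and were tested apart. Values were taken as log2(RPKM + 1), a scale that understates the change of low genes, and fitted with limma 3.58.1 in R 4.3.3, with a mean per accession, no block and empirical Bayes moderation with a trend over the mean level. All 38 libraries shared one estimate of the spread, with a prior of 4.63 degrees of freedom. An F test asked whether the 19 means differed. For 18 contrasts each accession was set against Col-0. A gene was called specific to an accession when it differed from the mean of the other 18 by at least 1 on the log2 scale and both libraries lay above, or both below, all other 36. The p-values of gene tests, list tests and gene pairs were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. Gene contrasts were adjusted within each contrast. List tests against Col-0, or against the other 18 accessions, were adjusted over all lists and contrasts together. Those p-values given below as permutation or exact p alone are not adjusted. The tests, 30 gene lists, 14 gene pairs for correlation, most alternatives and the rule for naming genes were fixed before the data were examined; the later ones are named as such. That rule takes the 12 genes with the widest range past the F test and up to 4 members of each list, the 10 genes past the threshold in the same direction in the most accessions and the gene with the largest difference from Col-0 in each, and the gene furthest above and below in each accession, with symbols before bare locus identifiers.

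Lists made from the annotation matched its product names, gene types and notes, and a note can mention a family that the gene is not part of. Notes alone brought in 107 of 289 F-box, 99 of 244 receptor-like, 83 of 316 ribosomal protein, 21 of 132 NLR, 17 of 48 defensin-like, 10 of 19 transposable element and 9 of 153 cytochrome P450 genes, so lists without them were tested as an alternative. A list was compared with all other tested genes by a 2-sided Fisher exact test on the share past the F test, and its median standard deviation between accessions was placed among 10000 random lists of its size drawn from 20 bins of mean level. Against Col-0, lists were tested with camera, a competitive test, at a preset correlation of 0.01 between genes over the 20453 genes with values in all 38 libraries; an estimated correlation and fry, a self-contained test, were the alternatives. Correlations over the 19 accession means used 100000 permutations, 2-sided, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Since the labels put accessions on lanes in blocks, the F test and correlations were also run within or centred on lane pairs. The share of 31-base words of a gene's exons found in another gene's exons was computed from the TAIR10.1 sequence, and genes above 5% are named below as uncertain, as are genes that overlap another. Words were matched on either strand, so exons that overlap those of another gene count as shared. The share thus does not separate paralogs from overlapping genes. Gene symbols and coordinates are those of the TAIR10.1 annotation.

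The steps were tested on simulated libraries with the real means and spread over 20453 genes, with changes of known size set in 1 accession. Of 100 genes changed by 2-fold, 32% passed the F test, 64% the contrast with Col-0 and 49% the criteria of an accession-specific gene; of those changed by 4-fold, 79%, 91% and 96% did. Among the unchanged genes 5, 13 and 2 calls were made. Alternatives included another pseudocount, other filters, 2 other scalings, a replicate block, other moderation, leaving out each library in turn, the code read as 0, libraries weighted by depth and annotation lists by product name alone. Plots were drawn with matplotlib 3.10.9.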

Results

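Seedling transcriptomes of 19 Arabidopsis accessions were compared, with 2 libraries for each, to show which genes differ in level among the founders, which differ from the reference accession Col-0 and which set a single founder apart. Values below are the mean RPKM ± SD of the 2 libraries of an accession (n = 2), and log2 differences are on the log2(RPKM + 1) scale. The estimated depth was 1240000 to 4920000 reads per library, so genes near 1 RPKM rest on few reads. A value of 0 is given as listed at 0, with no fold against it. The labels call the libraries of an accession biological replicates and do not say how plants were pooled.

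Libraries of one accession resembled each other more than those of any other accession. Over 20453 genes with values in all 38 libraries, the Pearson correlation across genes was 0.978 at the median between the libraries of an accession, from 0.962 in No-0 to 0.983 in Ct-1, and 0.946 at the median between accessions. The best match of 38 of 38 libraries was the other library of the same accession, against at most 6 in 100 draws of permuted labels. Genes are not independent replicates, so no p-value is attached to a correlation across genes. The 4 technical libraries of Col-0 correlated at 0.989 with each other and at 0.925 to 0.929 with the biological libraries of Col-0, which correlated at 0.979. Over 19983 shared genes the median SD was 0.14 among the 4 technical libraries and 0.14 among the 2 biological ones on the log2 scale. The median SD of 2 libraries falls further below the true spread than that of 4. The equal values therefore do not show an equal spread. Between the kinds 403 genes (2.02%) lay at least 4-fold apart.

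AT5G42530, an uncharacterised gene, reached 7600 ± 570 RPKM in Bur-0 and was listed at 0 in both Zu-0 libraries. AT2G25510, also uncharacterised, ranged from 0.277 ± 0.391 in Ler-0 to 4981 ± 916 RPKM in Mt-0. ECS1 stood at 1628 ± 185 RPKM in Bur-0 and at 0.253 ± 0.358 in Po-0. PR1, the classical marker of salicylic acid defence, was at 897 ± 71.4 RPKM in Bur-0 and listed at 0 in both Tsu-0 libraries. AT1G66100, a plant thionin, was at 508 ± 114 RPKM in Col-0 and listed at 0 in both libraries of 14 accessions. AT1G67105, a noncoding RNA, reached 379 ± 28.6 RPKM in Bur-0, AT3G62460, a putative endonuclease, 296 ± 10.4 in Can-0, and AT2G16367, a defensin-like gene, 273 ± 3.68 in Mt-0. N_new_gene_259, called new by the authors, reached 454 ± 248 RPKM in Mt-0, but its adjusted p of 0.0305 became 0.169 without Mt-0 replicate 1 and 0.114 without Mt-0 replicate 2.

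In all, 11440 of 20669 genes (55.3%) passed the F test over the 19 accessions, 205 of the 353 genes called new among them. Of those 11440 genes, 7520 spanned at least 1 on the log2 scale between the highest and lowest accession, 2470 at least 2 and 358 at least 4, with a median span of 1.24. The median residual SD was 0.23. Accessions that had shared lanes also differed from each other. Fitted alone, the lane pairs gave 2825 genes for Bur-0, Can-0, Col-0 and Ct-1, 3968 for Edi-0, Hi-0, Kn-0 and Ler-0, 825 for Mt-0, No-0, Oy-0 and Po-0, 1366 for Rsch-4, Sf-2, Tsu-0 and Wil-2, and 781 for Ws-0, Wu-0 and Zu-0. Of these, 2659, 3696, 790, 1321 and 747 were past the F test over all accessions. Of the variance of a gene, 19.9% lay between lane pairs at the median, 46.8% between accessions within a pair and 28.8% between replicates. Random assignments of accessions to lane pairs put 13.8% between pairs at the median, from 11.7% to 16.3%.

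Glucosinolates are sulfur compounds that deter herbivores, and their genes differed among accessions without exception. All 39 measured members of the glucosinolate biosynthesis list passed the F test, against 55.3% of other genes (Fisher exact adjusted p = 1.66e-09). AOP2, whose product makes alkenyl glucosinolates, stood at 636 ± 45.4 RPKM in Can-0 and at 1.03 ± 0.357 in No-0. AOP3, its neighbour, whose product makes hydroxyalkyl forms, was highest in Ler-0 at 191 ± 22.1 RPKM and listed at 0 in both Col-0 libraries. The 8 accessions with AOP3 at 37.3 RPKM or more were Ct-1, Kn-0, Ler-0, No-0, Po-0, Rsch-4, Tsu-0 and Wil-2, and the other 11 lay at or under 0.348. Of the 8, Po-0 had both transcripts, AOP2 at 195 ± 100 and AOP3 at 37.3 ± 21.8 RPKM, whereas Col-0 had AOP2 at 23.2 ± 5.87 RPKM. AOP2 lies on chromosome 4 at 1351688 to 1354096 on the minus strand and AOP3 at 1343845 to 1346436 on the plus strand of the TAIR10.1 annotation, the former with 5 exons and the latter with 7. AT2G25450, a dioxygenase gene known as the locus for hydroxylation of alkenyl glucosinolates, ranged from 0.120 ± 0.170 RPKM in Oy-0 to 1223 ± 46.3 in Zu-0. MYB29, a transcription factor for the aliphatic branch, was at 55.98 ± 3.25 RPKM in Sf-2 and listed at 0 in both Mt-0 libraries.

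**Figure D1:**
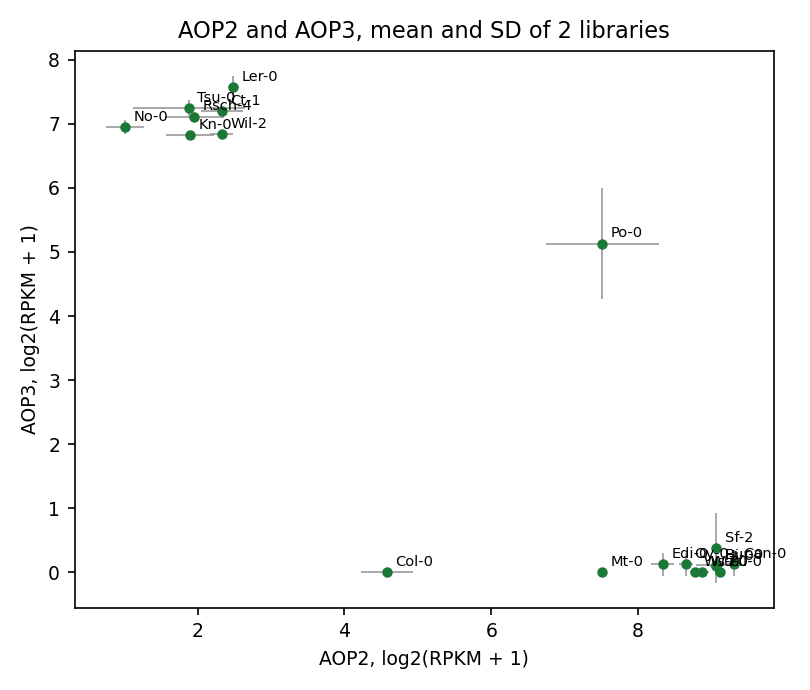
AOP2 (horizontal) against AOP3 (vertical), both as log2(RPKM + 1); each point is 1 accession, the mean of 2 libraries, and bars are the SD. Ler-0, at 4.61 RPKM of AOP2 and 191 of AOP3, sits at the upper left, Can-0, at 636 and 0.1001, at the lower right, and Po-0, at 195 and 37.3, stands apart from both sides.

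Glucosinolate hydrolysis genes varied as widely, and all 9 measured members passed (adjusted p = 0.0104). ESP, the epithiospecifier protein that turns hydrolysis towards nitriles, lay between 23.7 ± 3.65 RPKM in Kn-0 and 46.1 ± 4.36 in No-0 in a group with Col-0, Hi-0 and Rsch-4. It lay between 792 ± 151 in Wil-2 and 6575 ± 110 in Sf-2 in the other 14 accessions. TGG2, a myrosinase that cleaves glucosinolates, was at 774 ± 27.2 RPKM in Edi-0 and at 2.198 ± 1.01 in Hi-0, with 8 accessions at or under 4.98 and 11 at or above 285. ESM1, which favours isothiocyanates over nitriles, ranged from 12.5 ± 1.36 RPKM in Ws-0 to 967 ± 199 in No-0, and NSP3, a nitrile specifier, from 0.267 ± 0.0482 in Wu-0 to 5.42 ± 1.56 in Bur-0.

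In the flowering time list 21 of 32 measured members passed, a share not different from that of other genes (adjusted p = 0.366). FLC, the MADS-box repressor of flowering, was at 82.7 ± 9.75 RPKM or more in Ws-0, Edi-0, Can-0, Zu-0 and Sf-2, the last at 141 ± 3.39, and at or under 29.7 ± 0.670 in the other 14 accessions, the lowest being Oy-0 at 0.629 ± 0.0898. AGL20, also known as SOC1, an activator of flowering that FLC represses, was lowest in those same 5 accessions, from 0.317 ± 0.448 RPKM in Sf-2 to 1.23 ± 0.245 in Edi-0, and highest in Ler-0 at 30.1 ± 2.46. FLC spans 3173382 to 3179448 on the minus strand of chromosome 5 and overlaps the antisense gene AT5G01675, from which reads without strand cannot be separated. RAV2, a repressor of FT, was at 76.4 ± 15.4 RPKM in Edi-0 and 3.68 ± 0.245 in Rsch-4, and MAF3, a relative of FLC, at 19.4 ± 3.26 in Ct-1 and 0.452 ± 0.157 in Can-0.

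**Figure D2:**
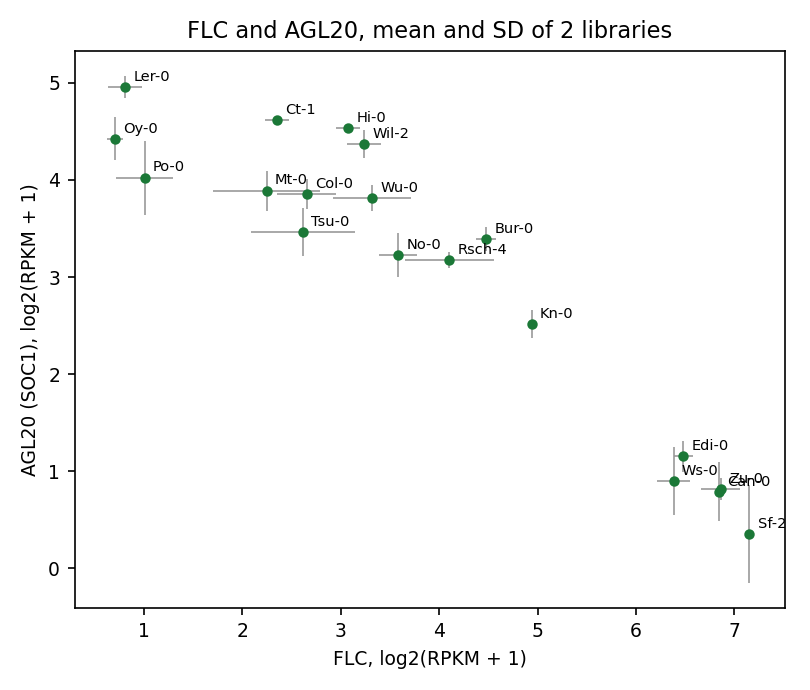
FLC (horizontal) against AGL20 (vertical), both as log2(RPKM + 1); each point is 1 accession, the mean of 2 libraries, and bars are the SD. Sf-2, Zu-0, Can-0, Edi-0 and Ws-0 lie at the lower right, with FLC at 82.7 RPKM or more, and Ler-0 lies at the upper left, with AGL20 at 30.1.

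Defence genes formed the next block. Of the salicylic acid defence list 27 of 28 members passed (adjusted p = 1.43e-05), 28 when adjusted over the list alone. ACD6, an ankyrin-repeat membrane protein that promotes this pathway, ranged from 0.519 ± 0.337 RPKM in No-0 to 194 ± 4.05 in Ct-1. AT5G10760, an aspartyl protease gene, and BGL2, a beta-glucanase known as PR2, were highest in Bur-0 at 151 ± 7.13 and 140 ± 15.4 RPKM and lowest in Hi-0 at 5.17 ± 1.43 and 5.04 ± 2.70. Of the jasmonate and ethylene defence list 21 of 23 passed (adjusted p = 0.00138). PDF1.2, a defensin, was at 39.4 ± 16.1 RPKM in Bur-0 and listed at 0 in both Ler-0 libraries, and VSP2, a vegetative storage protein induced by jasmonate, ranged from 6.32 ± 0.213 in Ler-0 to 192 ± 6.40 in Sf-2. Of the named resistance genes 21 of 23 passed (adjusted p = 0.00138). SNC1 and RPP5, immune receptors of one cluster on chromosome 4, reached 35.7 ± 1.92 RPKM in Sf-2 and 22.2 ± 1.79 in Wil-2. RPP5 was at 0.0279 ± 0.0395 in Bur-0 and SNC1 was listed at 0 in both Rsch-4 libraries. HR4, a homologue of the mildew resistance gene RPW8, was at 21.6 ± 7.43 RPKM in Col-0 and listed at 0 in both Hi-0 libraries. Over the annotation, 113 of 132 NLR resistance genes passed (115 when adjusted over the list alone; adjusted p = 4.67e-12), 174 of 244 receptor-like kinases and proteins (177; 2.45e-06) and 121 of 153 cytochrome P450 genes (123; 1.13e-08), all shares above that of other genes. CSA1, an immune receptor first found through a shade-avoidance mutant, reached 23.3 ± 1.42 RPKM in Edi-0, TIR, a protein with a Toll/interleukin receptor domain, 157 ± 14.3 in No-0, and HPL1, a hydroperoxide lyase of green leaf volatile synthesis, 70.3 ± 8.36 in Wil-2. TIR is in the receptor-like list through a match of its product name, so that list does not hold receptor-like kinases and proteins alone.

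Of the clock genes 18 of 19 passed (adjusted p = 0.00111), and their median SD between accessions, 0.92, exceeded that of 100% of random lists, whose median was 0.23. ELF4, part of the evening complex, was at 134 ± 4.87 RPKM in Zu-0 and 1.88 ± 0.513 in Mt-0. FKF1, a blue-light receptor of the photoperiod pathway, was at 58.2 ± 2.97 and 0.759 ± 0.232 in the same accessions. GRP7, an RNA-binding protein that peaks in the evening, ranged from 211 ± 36.2 RPKM in Ler-0 to 4053 ± 82.0 in Zu-0. CCA1, a morning gene, ran the other way, from 1.58 ± 0.641 in Zu-0 to 37.2 ± 0.692 in Mt-0. In No-0 the libraries themselves differed, with CCA1 at 23.3 and 2.92 RPKM, FKF1 at 4.85 and 67.4 and GRP7 at 420 and 3384 in replicates 1 and 2.

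**Figure D3:**
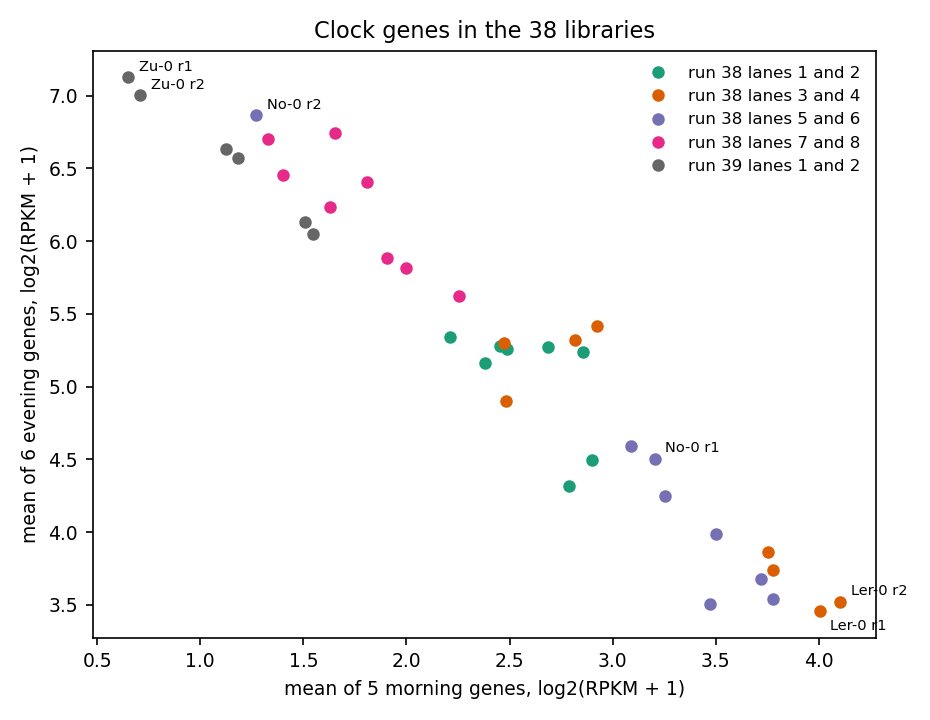
Mean of 5 morning genes (horizontal) against mean of 6 evening genes (vertical), both as log2(RPKM + 1), in the 38 libraries; colour gives the lane pair. Ler-0 lies at the lower right and Zu-0 at the upper left, and the No-0 libraries lie far apart on the same line.

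Among stress and nutrient lists, 16 of 21 cold and drought genes passed (19 when adjusted over the list alone; adjusted p = 0.104, though past the threshold without any of 9 single libraries, with 0.00181 without Rsch-4 replicate 1), with COR15B, a chloroplast protein induced by cold, from 8.92 ± 1.07 RPKM in Ler-0 to 198 ± 4.22 in Ws-0 and LTI78, known as RD29A, from 5.24 ± 0.499 in Kn-0 to 64.3 ± 24.7 in Tsu-0. Of the heat shock list 10 of 12 passed (adjusted p = 0.104, with 0.0140 without Kn-0 replicate 1 and past the threshold without any of 5 single libraries), and HSP70 was highest in Po-0 at 13.2 ± 0.303 RPKM and lowest in Zu-0 at 2.103 ± 0.153. The flavonoid list had 17 of 19 (adjusted p = 0.00546). PAP1, a MYB activator of anthocyanin synthesis, and DFR, an enzyme of the same pathway, were highest in Mt-0 at 16.2 ± 1.38 and 41.4 ± 5.38 RPKM. The phosphate starvation list had 12 of 14 (adjusted p = 0.0447, but 0.0843 without Ws-0 replicate 1, 0.0523 without Ws-0 replicate 2 and 0.0523 without Wu-0 replicate 2), with AT5G03545, a phosphate-responsive RNA, from 0.588 ± 0.263 RPKM in Bur-0 to 10.01 ± 3.27 in Wil-2. The iron list had 16 of 18 (17 when adjusted over the list alone; adjusted p = 0.00781), with FER1, an iron-storage ferritin, from 13.6 ± 0.207 RPKM in Wil-2 to 118 ± 30.7 in Tsu-0 and FRO3, a ferric reductase, from 0.622 ± 0.0760 in Tsu-0 to 25.04 ± 4.16 in Wil-2. The senescence list had 9 of 9 (adjusted p = 0.0104, lost without any of 8 single libraries, with 0.0754 without Col-0 replicate 1), with SAG13 at 30.2 ± 3.58 RPKM in Bur-0 and listed at 0 in both Ws-0 libraries. Loci of described natural variation, a list that shares AOP2, AOP3, ESP, ACD6 and FLC with those above, had 31 of 34 (32 when adjusted over the list alone; adjusted p = 3.53e-05).

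Photosynthesis genes passed often but moved little. Of 40 nuclear genes 32 passed (adjusted p = 0.00546), yet their median SD between accessions, 0.17, exceeded that of 4.67% of random lists. LHCB2.2, a light-harvesting protein, ranged from 635 ± 57.3 RPKM in Rsch-4 to 1907 ± 255 in Wu-0, and RBCS2B, a Rubisco small subunit, from 696 ± 59.6 in Wu-0 to 2321 ± 17.8 in Ler-0. Reference genes used for normalisation passed in 14 of 17 cases (adjusted p = 0.0447, lost without any of 16 single libraries, with 0.299 without Wu-0 replicate 2), with UBQ10 at 144 ± 3.77 RPKM in Ler-0 and 310 ± 14.3 in Can-0 and ACT8 at 42.4 ± 1.196 in Ler-0 and 90.8 ± 21.7 in Ws-0. Cytosolic ribosomal protein genes passed in 201 of 316 cases (210 when adjusted over the list alone; adjusted p = 0.00697, lost without any of 16 single libraries, with 0.665 without Wu-0 replicate 1), with AT3G48960, of the L13e family, from 0.471 ± 0.0638 RPKM in Can-0 to 53.1 ± 0.740 in Wu-0. F-box genes passed less often than other genes, 137 of 289 (133 when adjusted over the list alone; adjusted p = 0.0127, lost without any of 5 single libraries, with 0.108 without Ws-0 replicate 2). Of the 289, 107 are listed through an annotation note mentioning F-box, and among the 182 with F-box in the product name 94 passed (51.6%, adjusted p = 0.402), so the difference was lost.

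Markers of other tissues and cell types, defensin-like genes and transposable element genes did not pass more often than other genes. The counts were 4 of 8 root markers (adjusted p = 1), 3 of 4 flower and pollen markers (0.771), 3 of 5 seed markers (1), 4 of 8 stomatal lineage markers (1), 3 of 12 genes of cell division and the shoot meristem (2 when adjusted over the list alone; 0.0626, with 0.0137 without Oy-0 replicate 2 and past the threshold without any of 13 single libraries), 25 of 48 defensin-like genes (0.776) and 11 of 19 transposable element genes (13 when adjusted over the list alone; 1). The median SD of the defensin-like genes, 0.52, nevertheless exceeded that of 100% of random lists, whose median was 0.33, and that of the transposable element genes exceeded 41.6%. SEP3, a floral organ identity gene, was at 27.0 ± 0.604 RPKM in Rsch-4 and 0.351 ± 0.496 in Ws-0, PYK10, a beta-glucosidase abundant in roots, ranged from 84.2 ± 4.49 in Ct-1 to 435 ± 18.3 in Sf-2, and TMM, a receptor of the stomatal lineage, from 9.85 ± 0.904 in Edi-0 to 37.1 ± 0.0928 in Ler-0. For 17 of the 28 measured lists the count adjusted over the list alone was the same as that over all genes, and the other 11 are given above with both. Plastid and mitochondrial genes held no values in these libraries. Members of a list, tandem copies above all, are not independent. Values of FLC (79.1% of its exon words shared with another gene), RPP5 (55.2%), LHCB2.2 (40.4%), TIR (37.4%), RBCS2B (33.7%), SNC1 (32.1%), COR15B (28.8%), UBQ10 (17.5%), PDF1.2 (11.0%), PYK10 (10.9%), AT3G62460 (8.99%), MAF3 (8.18%), NSP3 (6.73%) and ESP (5.51%) are uncertain for that reason. So are those of FKF1, FRO3, FER1 and AT1G66100, which overlap another gene, as FLC, RPP5, COR15B and PYK10 also do.

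Against Col-0, each accession was tested alone to show where the founders depart from the accession of the reference. Col-0 held the fewest features without a value, and 99.7% of its low values had whole-number ratios, against 70.2% to 77.1% elsewhere. Any difference in processing between Col-0 and the rest would be shared by all 18 contrasts. N_new_gene_45, called new by the authors, was at 68.5 ± 12.3 RPKM in Col-0 and at most 6.56 in any other accession. AT1G63880, an immune receptor gene of the NLR class, was at 17.57 ± 1.76 RPKM in Col-0 and higher there in each contrast, with Wu-0, Kn-0 and Mt-0 at 11.96 ± 0.611, 11.6 ± 1.32 and 10.2 ± 0.969 and the other 15 accessions at or under 4.07. ACL, annotated as an acetone-cyanohydrin lyase, was at 213 ± 25.2 RPKM in Col-0 and at 32.3 to 131 in the others, and AT2G03980, a GDSL lipase, at 19.1 ± 2.09 and 1.87 to 10.5. AT5G55570, an uncharacterised gene, was lower in Col-0, at 9.997 ± 0.599 RPKM against 16.4 to 72.9, and AT5G64685, another, was listed at 0 in both Col-0 libraries and at 3.55 to 14.5 elsewhere. N_new_gene_304 (6.76 ± 0.260 RPKM in Col-0), AT4G02540, of the C1 domain family (11.3 ± 0.688), and AT1G67860 (79.0 ± 11.2) were each lower in all 18. Values of AT5G64685 (64.4% of its exon words shared, overlapping AT5G64680), AT4G02540 (overlapping AT4G02541) and AT5G55570 (overlapping AT5G55580) are uncertain.

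Of the 20669 genes, 9491 (45.9%) differed from Col-0 in at least 1 accession. The median over accessions was 1837.5 genes, from 1044 in Po-0 to 2841 in Zu-0, whose libraries shared 1 lane, and 51.3% of all calls were higher than Col-0. There were 17 genes past the threshold in the same direction in all 18 contrasts and 739 in at least 9, 325 of them higher than Col-0 and 414 lower. The count of 9491 rested on the control libraries, since without Col-0 replicate 2 it was 5851. The median became 1204 without Col-0 replicate 1 and 955.5 without Col-0 replicate 2. Leaving out 1 of the 2 libraries of an accession lowered its own count with 1 exception among 36 libraries, for example from 2841 to 1810 without Zu-0 replicate 1 or 1692 without Zu-0 replicate 2, and from 1044 to 594 without Po-0 replicate 1. The exception was No-0, whose count went from 1584 to 2047 without replicate 1. Such a step moved the own count by more than 1.5 times for 28 of 36 libraries.

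**Figure D4:**
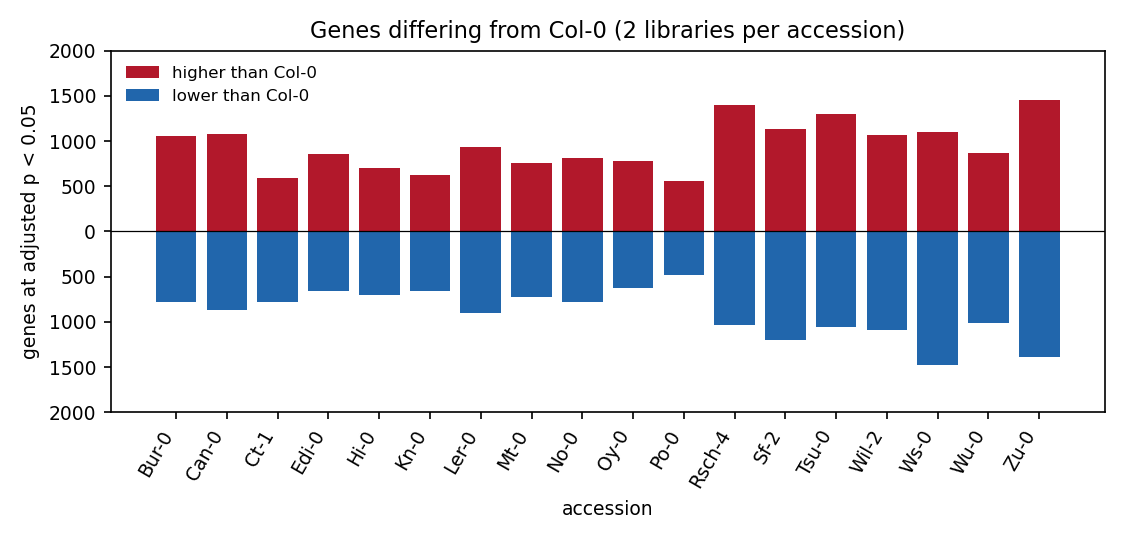
Number of genes past an adjusted p of 0.05 that were higher (up) or lower (down) than in Col-0, for the 18 other accessions with 2 libraries each. Zu-0 has the most, 1456 higher and 1385 lower, and Po-0 the fewest, 561 and 483.

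The gene with the largest difference from Col-0 was often one of a few. AT1G66100, the thionin, held this place in Bur-0, Can-0, Edi-0, Hi-0, Kn-0, Rsch-4 and Ws-0, where both libraries listed it at 0. ECS1 held it in No-0 (log2 difference -9.45 ± 0.36 SE), Oy-0 (-8.98), Po-0 (-10.07), Sf-2 (-9.63) and Tsu-0 (-9.29), with limma adjusted p from 2.87e-16 to 3.02e-15. AT1G67105, the noncoding RNA, was higher in Ct-1 by 8.03 ± 0.31, AT2G25510 lower in Ler-0 (-10.46 ± 0.37) and AT2G25450, the dioxygenase, lower in Wil-2 (-7.60 ± 0.24). AT2G16367, the defensin-like gene, was listed at 0 in both Col-0 libraries and stood out in Mt-0, and AT5G42530 was listed at 0 in both Zu-0 libraries. In Wu-0 the place fell to AT3G41768, annotated as 18S ribosomal RNA, at 827 ± 407 RPKM against 9.88 ± 8.61 in Col-0 (log2 difference 6.43 ± 0.57 SE, adjusted p = 1.53e-08); 96.5% of its words occur in another gene, so its values are uncertain.

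The 18 contrasts share the Col-0 libraries, so their calls overlap in part by construction. Among the 20453 complete genes 699 were called in the same direction in at least 9 contrasts, against 0.000776 expected of independent lists. The highest value in 20 simulations of unchanged accessions was 0, but their contrasts held a median of 0 calls, so this value says nothing of the overlap that shared controls give to real calls. For the 153 pairs of contrasts the median number of shared higher genes was 234 against 40.1 expected of independent lists, and of shared lower genes 258 against 33.0. The median correlation of log2 differences between contrasts was 0.427, below the 0.501 that shared controls alone gave, while the covariance was 0.131 against 0.0457, a difference of 0.0849. The controls were not split, since each part would hold 1 library, and part of the excess may come from them.

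At the preset correlation, though not with an estimated one, resistance genes as groups were higher in Col-0 than in most accessions. These contrasts share the same 2 Col-0 libraries and are not independent. Only genes with values in all 38 libraries entered, which kept 115 of 132 measured NLR genes and 19 of 23 named resistance genes. Of 504 tests of a list in an accession, 142 passed with camera at the preset correlation, 29 higher and 113 lower; with an estimated correlation 21 held, all lower. Against the mean of the other 18 accessions in place of Col-0, 102 of 532 tests passed, 54 higher and 48 lower, and 59 of the 142 calls were kept. Named resistance genes were lower in 17 accessions, in 9 of them also with an estimated correlation; in Hi-0 the median was -0.57, with 7 of 19 members lower and 0 higher (camera adjusted p = 2.70e-08, and 0.00955 with an estimated correlation). In Edi-0 the median of that list was 0.03 although the test pointed down, as its mean did (-0.39). NLR genes of the annotation were lower in 15 accessions, in Sf-2 with 34 of 115 members lower and 8 higher, and none held, the adjusted p with an estimated correlation being 0.115 at the least; in Kn-0 and Mt-0 their median was 0. Without Col-0 replicate 2 named resistance genes were lower in 15 accessions and NLR genes in 13. Against the mean of the other 18, named resistance genes were higher in Col-0 (adjusted p = 3.09e-09, and 0.00831 with an estimated correlation) and Bur-0 (0.0130) and lower in No-0 (0.00108), and NLR genes were higher in Col-0 (3.90e-06), Bur-0 (0.00183) and Edi-0 (0.0345) and lower in Hi-0, No-0 and Rsch-4 (0.0210, 0.0172 and 0.0493). Apart from named resistance genes in Col-0, none of these held with an estimated correlation (adjusted p = 0.209 at the least). Loci of described natural variation were lower in 11 accessions, 9 of them with an estimated correlation. Glucosinolate hydrolysis genes were lower in 4 accessions, Hi-0, Kn-0 and Ler-0 with an estimated correlation too (adjusted p = 0.00955, 0.00955 and 0.0132), and Rsch-4 without it (0.119).

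Every call of the remaining lists against Col-0 was lost with an estimated correlation. That statement does not cover their calls against the mean of the other accessions. Salicylic acid defence was lower in 13 accessions, most in Hi-0 (median -1.23, 14 of 28 members lower and 0 higher, camera adjusted p = 1.07e-14; adjusted p = 0.0822 with an estimated correlation), and higher in Bur-0 (median 0.95, 13 higher and 0 lower, 1.71e-12; 0.115) and Mt-0 (0.95, 8 higher and 1 lower, 3.20e-06; 0.296). Glucosinolate biosynthesis was higher in Sf-2, Zu-0, Bur-0, Can-0 and Wu-0 and lower in Ct-1, Wil-2, Ws-0, No-0 and Mt-0, with adjusted p from 0.115 to 0.535 with an estimated correlation. Cold and drought genes were higher in 8 accessions, Tsu-0 first with a median of 1.00 and 12 of 21 members higher, and lower in Ler-0 (0.115 to 0.549). Nuclear photosynthesis genes were lower in 13 accessions (0.191 to 0.642), flavonoid genes in 11 (0.115 to 0.443), senescence genes in 7 (0.115 to 0.250) and reference genes in 5 (0.436 to 0.522). Phosphate starvation genes were higher in 4 accessions (0.101 to 0.237), cytosolic ribosomal protein genes higher in 5 and lower in 2 (0.575 to 0.883), and jasmonate and ethylene defence higher in Bur-0 and Mt-0 and lower in Hi-0 (0.541 to 0.685). Iron genes were higher in Zu-0 and lower in Tsu-0 (both 0.372), flowering time genes lower in Po-0 and Oy-0 (0.214 and 0.312), receptor-like genes lower in Hi-0, Tsu-0 and No-0 (0.115 to 0.228; by product name alone in 7 accessions, 2 of them with an estimated correlation, 0.0157 at the least) and heat shock genes lower in Oy-0 (0.240). Seed markers were higher in Po-0 (median 2.08; 0.143), stomatal markers higher in Ler-0 (median 0.90; 0.0733) and genes of cell division lower in Mt-0 (median -0.36; 0.429). Clock, root, flower and pollen, F-box, cytochrome P450, defensin-like and transposable element lists passed in no accession at the preset correlation. For the clock list this decides little, since camera tests for a shift in a shared direction. That list holds morning and evening genes, which ran opposite over the accessions (r = -0.973) and so cancel.

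Differences from Col-0 went with the level of clock genes. A score was taken as the mean of 6 evening genes (TOC1, ELF4, PCL1, FKF1, GI and GRP7) minus that of 5 morning genes (CCA1, LHY, RVE8, RVE1 and PRR9) on the log2 scale; it was chosen after the data were seen. Values of PRR9 (32.7% shared words), PCL1 (16.9%), RVE1 (10.4%) and FKF1 are uncertain, and the last 3 overlap another gene. The score ran from -0.56 in Ler-0 to 6.38 in Zu-0. Over 18 accessions its distance from Col-0 correlated with the number of genes called (Pearson r = 0.863, permutation p = 4.00e-05; Spearman rho = 0.763, permutation p = 0.000490; adjusted over 6 relations 8.00e-05 and 0.000980), at 0.765 without the 2 extremes (permutation p = 0.000810) and at 0.617 when centred on lane pairs (permutation p = 0.0246).

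Some genes were highest or lowest in both libraries of a single founder, at times with a second accession close to it. PR1 in Bur-0 (log2 difference from the other 18 of 6.39 ± 0.74 SE, adjusted p = 6.78e-07; Mt-0 was at 432 ± 197 RPKM and the rest at or under 83.4), ACD6 in Ct-1 (3.41 ± 0.23) and EARLI1, a lipid-transfer-like protein, in Po-0 (3.32 ± 0.39) were the leading higher genes with a symbol in those accessions. TGG2 in Edi-0 (3.91 ± 0.16), AOP3 in Ler-0 (4.89 ± 0.18) and ESM1 in No-0 (3.86 ± 0.08) were those of glucosinolate metabolism. A large difference from the mean of the other 18 need not be a wide lead over the next accession. The highest other mean was 141 RPKM for ACD6, against 194 in Ct-1, and 567 for TGG2, against 774 in Edi-0. For AOP3 it was 151, against 191 in Ler-0, and for ESM1 441, against 967 in No-0. FLC led in Sf-2 (3.50 ± 0.18, at 141 RPKM with 116 as the highest other mean). QQS, a starch-related gene without known relatives outside the species, led in Rsch-4 (5.25 ± 0.31, with Edi-0 at 52.5 ± 7.15 RPKM and the rest at or under 7.39), and COR27, a cold-regulated gene of the clock, in Zu-0 (4.01 ± 0.51). Among lower genes, UBC8, a ubiquitin-conjugating enzyme, was at 1.78 ± 0.420 RPKM in Oy-0 against at least 95.6 in every other accession (-5.43 ± 0.10, adjusted p = 1.52e-21), and ARGAH2, an arginase, at 0.110 ± 0.156 in Can-0 (-6.54 ± 0.23) and 2.41 ± 2.56 in Sf-2, against at least 73.4 in the rest. MYB29 was listed at 0 in both Mt-0 libraries against at least 6.94 RPKM elsewhere. AOP2 was lowest in No-0 (-5.25 ± 0.21, at 1.03 RPKM with 2.76 as the lowest other mean) and ESM1 in Ws-0 (-2.63 ± 0.08, at 12.5 with 24.8).

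Altogether 2485 such cases in 2294 genes met the criteria, 1572 higher and 913 lower, so 63.3% were higher. Bur-0 had the most, 263 higher and 56 lower, followed by Can-0 (156 and 80), Edi-0 (168 and 40) and Zu-0 (102 and 105), and Po-0 the fewest (25 and 14). COPT2, a copper transporter, was lower in Sf-2 (-4.16 ± 0.24), GPX7, a glutathione peroxidase, lower in Ct-1 (-4.09 ± 0.24), PLA2A, a phospholipase, lower in Tsu-0 (-3.86 ± 0.23) and CRL2 lower in Zu-0 (-3.23 ± 0.16, with Can-0 at 1.82 ± 0.248 RPKM and the rest at or above 9.53). PAP8, a purple acid phosphatase, was lower in Bur-0 (-3.20 ± 0.15), VSP2 lower in Ler-0 (-2.85 ± 0.26, with Wu-0 next at 9.90 ± 4.31 RPKM), LHCB2.3, a light-harvesting gene with 40.8% shared words, lower in Edi-0 (-2.92 ± 0.21) and AOC2, an enzyme of jasmonate synthesis, lower in Hi-0 (-2.17 ± 0.21). Values of FLC (79.1% shared words), GPX7 (47.3%), LHCB2.3 (40.8%), SNC1 (32.1%) and UBQ13 (19.8%) are uncertain, as are those of EARLI1, and all of these but SNC1 overlap another gene. HR4 was higher in Col-0 (3.32 ± 0.35), whereas IMS2, known as MAM3 in glucosinolate chain elongation, was lower there (-1.58 ± 0.12, with Mt-0 next at 20.7 ± 2.04 RPKM). ELIP2, a chlorophyll-binding protein induced by strong light, was higher in Kn-0 (2.62 ± 0.31), and AGL94, a MADS-box gene, higher in Wu-0 (4.11 ± 0.20). UBQ13, listed at 0 in every other library, was at 16.7 ± 2.91 RPKM in Can-0, and SNC1 was listed at 0 in both Rsch-4 libraries and was at 0.187 ± 0.0378 in Mt-0, with no value in Can-0. A lone library meets the rank criterion more easily than a pair, and own counts went up when a replicate was left out. The rise was largest in Ws-0 without replicate 1, which left replicate 2, the library of lowest estimated depth (1240000 reads). Without Ws-0 replicate 2 instead, the rise was much smaller. Low depth and the lone library therefore cannot be told apart there.

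Pairs of genes fixed before the data were examined were correlated over the 19 accession means; 11 of 13 pairs passed with Pearson's r, and 8 with Spearman's rho. FLC and AGL20 ran opposite (r = -0.935, rho = -0.907, both with permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 4.33e-05), at -0.909 without Sf-2 and Zu-0 and at -0.946 when centred on lane pairs. CCA1 and TOC1, the opposite arms of the clock, did so too (r = -0.963, rho = -0.947, adjusted permutation p = 4.33e-05; -0.946 without Zu-0 and Ws-0 and -0.896 centred). DFR and LDOX, enzymes of anthocyanin synthesis, went together (r = 0.887, rho = 0.872, adjusted permutation p = 4.33e-05; 0.859 and 0.825), as did PR1 and BGL2 (r = 0.866, rho = 0.768, adjusted permutation p = 6.50e-05 and 0.000845; 0.690 and 0.889). MYB29 and CYP79F1, an enzyme under its control, correlated at r = 0.760 and rho = 0.714 (adjusted permutation p = 0.000364 and 0.00213; 0.613 and 0.736), and COR15A and KIN1, both induced by cold, at 0.649 and 0.658 (0.00609 and 0.00615; 0.734 and 0.634).

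The remaining pairs held less well. ACD6 and PR1 correlated at r = 0.636 and rho = 0.619 (adjusted permutation p = 0.00609 and 0.0108) and at 0.667 without the 2 extremes, but not within lane pairs (0.494, adjusted permutation p = 0.141). FRI, an activator of FLC, and FLC correlated at r = 0.514 and rho = 0.528 (adjusted permutation p = 0.0376 and 0.0349; 0.497 without 2 extremes and 0.656 centred). EDS1 and PR1 (r = 0.573, rho = 0.425, adjusted permutation p = 0.0162 and 0.0925) rested on Bur-0 and Can-0, with r = 0.374 without them and 0.465 centred. bHLH38 and IRT1, of iron uptake (r = 0.503, rho = 0.489, adjusted permutation p = 0.0384 and 0.0527; 0.461 centred), rested on Zu-0 and Sf-2, with 0.224 without them. SPX1 and MGDC, of phosphate starvation (r = 0.490, rho = 0.332, adjusted permutation p = 0.0384 and 0.166; 0.552 centred), rested on Wil-2 and Wu-0, with 0.145 without them. FLC and FT did not pass (r = -0.439, rho = -0.401, adjusted permutation p = 0.0654 and 0.0958; -0.354 without 2 extremes), though they did when centred on lane pairs (-0.693, adjusted permutation p = 0.0188). FT reached at most 0.96 and IRT1 at most 1.51 on the log2 scale in any accession, levels near the floor of 3 reads (0.406 to 1.61 RPKM). MYB28 and BCAT4 did not pass either (r = -0.418, rho = -0.404, adjusted permutation p = 0.0744 and 0.0958; -0.354 without 2 extremes and -0.0424 centred). AOP2 falls into clusters and was given no pooled r; against AOP3 it reached -0.589 in the 11 accessions with high AOP2 (permutation p = 0.152) and -0.872 in the 8 with low AOP2 (exact p = 0.106). Values of bHLH38 (35.6% shared words), BCAT4 (23.5%), FRI (8.52%), LDOX (6.72%) and KIN1 (6.22%) are uncertain, and the first 3 of these overlap another gene.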

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

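The pairs of accessions set against each other here were chosen only after the differences from Col-0 were seen, as were their tests. The p-values therefore restate a choice made on the same values, are too small, and serve as description alone. In 6 lists the test against Col-0 passed upward in one accession and downward in another, and such accessions were then compared directly with camera. Genes of salicylic acid defence were higher in Bur-0 than in Hi-0 by a median of 2.58 on the log2 scale, with 28 of 28 members higher (adjusted p = 2.16e-32 at the preset correlation and 0.00106 with an estimated correlation). Cold and drought genes were higher in Tsu-0 than in Ler-0 by 1.195, in 19 of 21 members (3.82e-13; adjusted p = 0.00441 with an estimated correlation). Iron genes were higher in Zu-0 than in Tsu-0 by 1.01, in 13 of 18 members (4.95e-07; adjusted p = 0.00618 with an estimated correlation), and glucosinolate biosynthesis genes higher in Sf-2 than in Mt-0 by 0.56, in 26 of 39 (4.28e-11; adjusted p = 0.00441 with an estimated correlation). Genes of jasmonate and ethylene defence were higher in Bur-0 than in Hi-0 by 1.08, in 20 of 23 (2.03e-09), and cytosolic ribosomal protein genes higher in Wu-0 than in Edi-0 by 0.35, in 255 of 313 (3.82e-13). Neither held with an estimated correlation (adjusted p = 0.0642 and 0.119).

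Signal also appeared in values that no comparison used. In the 4 technical libraries of Col-0, 78 of 133 plastid genes reached 1 RPKM in every library and took 7.76% to 8.65% of the summed RPKM, with ATCG00470 highest at 12161 ± 612 RPKM (n = 4). Of 146 mitochondrial genes 27 did so, with 0.102% to 0.106% of the sum and ATMG00030 highest at 611 ± 14.7 RPKM (n = 4). Among 893 transposable elements tested apart, 221 (24.7%) passed the F test over the 19 accessions, and Can-0 was the highest accession most often, for 21 of them.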

How the results depend on the processing

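The reading of the no-value code as 0, the weighting of libraries by depth, the estimated correlation for lists against the other 18 accessions, annotation lists by product name alone and the centring of correlations on lane pairs were chosen after the data were seen. Counts of genes among accessions, against Col-0 and specific to an accession stayed within 1.5 times their value under another pseudocount, 2 other filters, quantile or median-ratio scaling, other moderation, the code as 0 and depth weights; with the last, 11242 genes differed from Col-0. The replicate numbers did not pair the libraries: within lane pairs the deviations of equally numbered libraries correlated at 0.00195 on average (-0.109 to 0.114, 27 pairs), and with a replicate block the counts were 11234, 9377 and 2482 genes, 18 lists and 141 list tests. With annotation lists by product name alone, 17 lists passed among accessions, without the F-box list, and 144 tests against Col-0 passed, with 140 of the 142 calls kept and NLR genes lower in 13 accessions. Under quantile scaling 121 list tests against Col-0 passed, 28 higher and 93 lower, all of them among the 142.

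What moved further was as follows, and the cause was not tested unless named. Genes differing from Col-0 were 5780 at an adjusted p of 0.01 and 2122 with 4 libraries in each fit, which leaves 2 residual degrees of freedom. Within lane pairs, with 3 or 4 accessions each, the F test gave 2825, 3968, 825, 1366 and 781 genes. The share of variance between lane pairs was 15.9% without the run 39 pair, 7 of 13 correlations passed without the 2 extreme accessions, and 21 list tests against Col-0 passed with an estimated correlation. With fry, which does not compare a list with other genes, 163 passed, 51 higher and 112 lower, among them 106 of the 142. Leaving out each library gave 10785 to 11878 genes among accessions, 5851 to 10100 against Col-0, the lowest without Col-0 replicate 2, 2539 to 3109 specific cases, 14 to 20 lists among accessions and 129 to 147 list tests against Col-0. Of 8124 values of named genes under alternatives, 8073 kept their side of the threshold, 51 lost it and 0 reversed. Many of these values are ranges among accessions, which cannot reverse by construction. The 0 therefore speaks only for differences from Col-0 or from the other accessions. Median-ratio scaling moved the share of higher calls in Rsch-4 from 57.4% to 46.3%, so that lower calls outnumbered higher ones. Scaling moved the median gene by at most 0.0716 on the log2 scale. A lone library left in an accession was taken to vary like the others. Not run were a fit to nuclear genes alone, since organelle genes hold no values, the technical mean as a further Col-0 library, which comes from another feature set, and count tests. Depth limits genes near the floor of 0.406 to 1.61 RPKM for 3 reads.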

Other observations

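The search for genes listed at 0, the lists by product name alone and the tests of clock phase, lane pair, gene length and random lane pairs with and without the run 39 pair, of depth over accessions, of NLR genes against all genes and of accession-specific genes by midpoint were chosen only after the results were seen; the others were set beforehand. Of 11121 genes with at least 10 RPKM in both libraries of an accession, 304 (2.73%) were listed at 0 in both libraries of another, 71 of them in a single accession and 102 in 9 or more. New genes made up 50 of the 304, out of 71 that reached 10 RPKM. Defensin-like genes (6 of 13, Fisher exact adjusted p = 1.51e-05), NLR genes (7 of 27, 7.68e-05) and F-box genes (7 of 69, 0.0233) did this more often than other genes, among them AT2G16367, PDF1.2, CSA1 and SNC1. The F-box list member AT5G33330 (6.30% shared words, overlapping AT5G33320) is a ribonuclease H-like gene by product; by product name alone the counts were 4 of 7 (0.000224), 6 of 20 (0.000224) and 5 of 37 (0.0262).

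Clock genes ordered the accessions along the widest axis of the data, the first component (13.4% of the variance), with which the clock score correlated at 0.930. GC content (rho = 0.0616 with gene loadings) and gene length (0.00547) argue against those technical trends, and a candidate explanation is that seedlings were at different clock phases, since morning and evening genes ran opposite (r = -0.973). Depth stays open: replicate differences in depth and score correlated at 0.00742 (standard error 0.144), but that bound leaves out differences between accessions, over which they correlated (r = -0.478, permutation p = 0.0392; rho = -0.488, permutation p = 0.0365; adjusted over 6 relations 0.0470 and 0.0438; -0.440 without 2 extremes, permutation p = 0.0762; -0.221 centred on lane pairs, permutation p = 0.317). Within lane pairs the score varied 1.58 times as much as between replicates, which decides nothing, and 3.33 times without No-0, whose libraries scored 1.303 and 5.59, which argues against lane pair as the whole cause in the other 18 accessions. Scores also separated by lane pair. Rsch-4, Sf-2, Tsu-0 and Wil-2, which shared a pair, and the run 39 accessions scored from 3.59 (Wil-2) to 6.38 (Zu-0). Every other accession scored lower, with No-0 at 3.45 and Ct-1 next at 2.95. Accession and lane pair are partly confounded, so lane pair stays open as part of the cause. Hour of harvest and genotype stay open as sources of phase among accessions, and neither was tested. The No-0 libraries carry the same accession label, so genotype as labelled does not account for the gap between them.

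The share of variance between lane pairs, 19.9%, was reached by 1 of 100 assignments, the real one, and the highest other gave 16.3%. Chance is therefore an unlikely source of that share, but 100 assignments cannot exclude it. Without the run 39 pair the share was 15.9%, again reached by 1 of 100, the real one, with 14.1% as the highest other.

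NLR genes were below Col-0 in 15 accessions at the preset correlation, and in none with an estimated correlation (adjusted p = 0.115 at the least). Sequence divergence from the reference could lower every other accession, and Col-0 was highest for 11 of 132 genes, 3.27 times the 3.37 expected from its share of all genes and above the 6.95 of an even split. Bur-0 was highest for 26 (3.25 times) and Edi-0 for 16 (2.32 times). The bound set beforehand takes 2 other accessions above Col-0 as counting against divergence. Because 16 lies within counting spread of 11, a criterion outside that bound, divergence is left open. Reads shared between paralogs cannot be told apart from a true difference, as the 69 members with under 5% shared words had a median of -0.0530 (standard error 0.0455), all members -0.0982. By the bound set beforehand the former median would count against shared reads, but its standard error reaches past that bound. The means of the salicylic acid and NLR lists correlated (r = 0.568, permutation p = 0.0126; rho = 0.604, permutation p = 0.00723; adjusted over 6 relations 0.0190 and 0.0108; 0.703 without 2 extremes), so the defence state of the seedlings is a candidate explanation, although within lane pairs r was 0.366 (permutation p = 0.211).

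Genes specific to an accession were higher in 63.3% of cases. Whether the floor of the log scale produces this stays open, as the answer turned on how level was split. Among 594 cases with a mean log2 level of at least 4, a split that puts losses on the upper side, the share was 43.4%, and among 637 with a midpoint of the accession and the others of at least 4, a split that draws gains from the more numerous low genes, it was 66.4%. Shared reads of paralogs are argued against as the whole cause, since the share was 60.9% among 1704 cases with under 5% shared words. Without Bur-0 it was 60.4%, and without Bur-0, Can-0 and Edi-0 57.2%; no biological explanation was tested.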
